A study of Mus musculus with 6 samples.

How the data were processed

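RNA of mouse OT1 CD8+ T cells was measured by bulk RNA sequencing in 6 libraries, 3 from cells with an empty overexpression vector and 3 from cells with a PTMA overexpression construct, all 48 h after OVA peptide. Per the labels' protocols, poly(A) RNA was isolated from total RNA, fragmented, reverse-transcribed and sequenced in pairs on an Illumina NovaSeq instrument. The extraction protocol speaks of an adipose type, which does not match CD8+ T cells. The groups and the replicate numbers 1 to 3 were taken from the sample titles. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

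The authors deposited one table of 27480 genes with raw counts per gene and library, whole numbers that are not normalized, per the file headers. The same deposited table holds FPKM per gene and library, fragments scaled by gene length and library size, per the file headers. Over 10141 genes with at least 200 counts in every library, the ratio of count to FPKM differed between libraries by a single factor per library. The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0, Bowtie 0.12.2 and the build mm8, with no role or order. The counting program, its use of strand and its treatment of reads with several matches are not given in the sources used here. The gene coordinates of the table are those of GRCm38 and not mm8: of 27405 identifiers found in GENCODE M21, 99.7% shared a gene start or end with it. Coordinates are therefore given as the table lists them, on GRCm38. Every row of the table had at least 1 count. Total counts were 54989408, 62995824 and 63011584 for vector 1 to 3 and 65548729, 66767589 and 65640178 for PTMA 1 to 3. A count of 0 allows up to 3 counts, which is 0.0449 to 0.0546 CPM (the usual abbreviation for counts scaled by library size) in a single library. This floor covers counting error only.

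Because the table held counts, the test set out for that case was used in place of limma on FPKM: edgeR 4.0.16 (R 4.3.3) with TMM scaling, its filterByExpr function (minimum count 10) and the quasi-likelihood test, with group as the only term and all 6 libraries. This left 16592 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and log2 fold changes are PTMA minus vector. CPM values are TMM-scaled and given as mean ± SD with n = 3 per group.

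The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The named genes are Ptma, then up to 10 genes per direction with the largest fold change among those past the threshold whose groups do not overlap, leaving out predicted and unnamed genes (0 were left out). From each pathway list the rule took up to 4 members past the threshold or, where none passed, the member with the smallest p-value. A gene that this rule takes is not reported here. There were 27 pathway lists and 7 lists of cell type markers. Some list members have no row in the table and were not analysed here. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the inter-gene correlation preset to 0.01, and beside it with an estimated correlation and with fry. Camera compares a list with all other genes, whereas fry asks whether its genes move one way on balance. GO and KEGG terms given in the table were tested in the same way where 15 to 300 of their genes were tested. A further 7 lists, of oocyte, granulosa, embryo, testis and mature dendritic cell genes, were written after the genes with the smallest p-values had been seen. They serve as descriptions and, in the closing section, in tests against bounds, and the rule of the dendritic test was changed more than once after its values were seen, the margin of 2 SE being the last form.

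The alternatives were other scalings of the counts, robust edgeR, no filter, a replicate block, leaving out each library in turn, and DESeq2 1.42.0. Limma was also run on log2(FPKM + 1) with other pseudocounts, filters, quantile normalization, no trend and array weights. The procedure was tested on simulated counts for the 16592 genes with 200 changed genes, all taken from genes with a mean above 1 CPM. The shares recovered therefore do not cover rarer genes. In that simulation of the comparison of PTMA with vector, edgeR recovered 46.3% of 67 genes changed 1.5-fold, 74.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and called 14 unchanged genes. DESeq2 recovered 55.2%, 79.1% and 100% and called 47 unchanged genes. With no list shifted, camera called 0 of 27 lists, and with the S phase list shifted by 0.1 on the log2 scale it called that list alone. The simulated genes varied independently, so this does not show how often camera calls lists whose genes vary together. Libraries of a group were compared for duplication: between replicates the chi-square per gene was 22.5 to 122, far above the value of 1 that sampling noise gives, so each was kept as its own sample.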

Results

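The data are gene counts of 6 libraries of OT1 CD8+ T cells, mouse killer T cells whose transgenic receptor recognises a peptide of ovalbumin (OVA). In 3 libraries the cells carried an empty overexpression vector and in 3 a construct for PTMA (prothymosin alpha, a small acidic nuclear protein). All cells had been stimulated with OVA peptide for 48 h. Total counts ran from 54989408 to 66767589 per library. The design implies a single comparison, PTMA against vector, and the series title places it in the question of how PTMA bears on the mitochondria and persistence of CD8+ T cells.

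Ptma itself (ENSMUSG00000026238, chromosome 1, 86526726 to 86530712 on GRCm38) stood at 926 ± 193 CPM (SD, n = 3) in the vector libraries and 1257 ± 98.0 CPM (SD, n = 3) in the PTMA libraries, 1.36-fold as high. The vector libraries had 848, 783 and 1146 CPM and the PTMA libraries 1152, 1346 and 1272 CPM, so the lowest PTMA library lay just above the highest vector library. The log2 fold change was 0.44 (SE 0.13) and did not pass the test (edgeR quasi-likelihood, adjusted p = 0.951). Without vector 3 it was 0.62, with an adjusted p of 0.0724. Ptma has processed pseudogenes that can share its reads, and the labels do not give the species of the construct, so whether its RNA is counted under the mouse gene is open.

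Of 16592 genes tested, 2 changed, and both fell in the PTMA libraries. Gdf9, a growth factor secreted by oocytes, fell 15-fold, from 18.8 ± 6.12 to 1.25 ± 0.63 CPM (SD, n = 3 per group). Pkd2l2, a channel protein of the polycystin family, fell 2.75-fold, from 8.82 ± 0.14 to 3.21 ± 0.37 CPM (SD, n = 3 per group). Each was lower in all 3 PTMA libraries than in any vector library. Gdf9 (ENSMUSG00000018238, chromosome 11, 53431023 to 53436902) had a log2 fold change of -3.90 (SE 0.39). Pkd2l2 (ENSMUSG00000014503, chromosome 18, 34408489 to 34441794) had one of -1.46 (SE 0.15). The adjusted p was 0.0397 for both (edgeR quasi-likelihood, Benjamini-Hochberg). No other gene of GENCODE M21 overlaps either of them.

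At an unadjusted p under 0.05 there were 771 genes, 319 higher and 452 lower. This is less than the share of 0.05 of the 16592 tested genes that chance gives. Other splits of the 6 libraries into 3 and 3 gave 262 to 2672 such genes. The balance of higher and lower genes depended on the scale and on which genes were tested. It was 197 higher and 557 lower under libraries scaled to the same sum. With limma on log2(FPKM + 1) it was 287 higher and 155 lower over 10960 genes with a mean FPKM of at least 1. It was 367 and 364 over 16601 genes with a mean FPKM of at least 0.1, and 225 and 51 over 6897 genes with one of at least 5. The groups did not overlap for 1787 genes, 10.8% of those tested, where chance gives 10%. DESeq2 called 42 genes, 7 higher and 35 lower. With edgeR no gene passed without vector 1, without PTMA 1 or without PTMA 3.

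**Figure D1:**
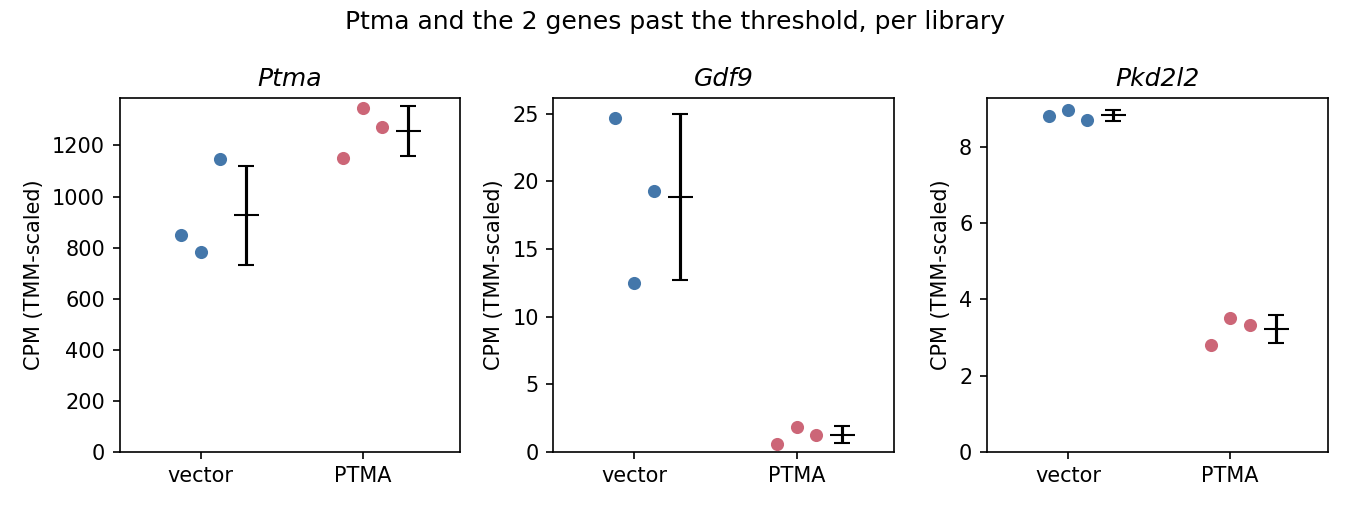
Level of Ptma, Gdf9 and Pkd2l2 in TMM-scaled CPM (vertical axes, from 0) in the vector and PTMA libraries (horizontal axes). Points are single libraries and the black marks are the mean and SD of 3 libraries; Gdf9 and Pkd2l2 lie lower in all 3 PTMA libraries, and for Ptma the 1146 CPM of vector 3 nearly reach the 1152 CPM of PTMA 1.

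Genes of the cell cycle were slightly higher as groups in the PTMA libraries. In the S phase list, which holds DNA replication factors such as the Mcm helicase subunits, 23 of 26 members had positive log2 fold changes, with a median of 0.13. The list passed the set test (camera, adjusted p = 6.62e-07), but not with an estimated correlation (adjusted p = 0.0951 with an estimated correlation), while fry gave an adjusted p of 0.0235. Its pooled level was 6085, 6086 and 6311 CPM in vector 1 to 3 and 6749, 6854 and 6697 CPM in PTMA 1 to 3. In the G2M list of mitosis genes 21 of 26 members were positive, with a median of 0.10 (camera, adjusted p = 1.61e-05; adjusted p = 0.511 with an estimated correlation). The mitotic kinase Plk1 stood at 231 ± 5.44 and 271 ± 10.4 CPM (SD, n = 3 per group) in vector and PTMA. No member of either list passed over all genes, and 0 passed adjusted over the list alone. Both lists passed camera in all 19 alternative fits.

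Of the lists on mitochondria, 6 passed camera in the higher direction, each by a few percent. In the mitochondrial ribosome list 53 of 59 members were positive (median log2 fold change 0.07, adjusted p = 0.000266; adjusted p = 0.78 with an estimated correlation). In the tricarboxylic acid cycle list 16 of 18 were positive (median 0.10, adjusted p = 0.00156; adjusted p = 0.484 with an estimated correlation). Protein import and chaperones had 22 of 27 positive (adjusted p = 0.00156; adjusted p = 0.579 with an estimated correlation), and fatty acid oxidation 15 of 17 (adjusted p = 0.00491; adjusted p = 0.579 with an estimated correlation). Complex I of the respiratory chain had 24 of 37 positive (adjusted p = 0.0203; adjusted p = 0.78 with an estimated correlation), and dynamics and mitophagy 18 of 24 (adjusted p = 0.0288; adjusted p = 0.511 with an estimated correlation). Over the 19 alternative fits the tricarboxylic acid cycle list passed in 17, the mitochondrial ribosome and protein import lists in 16 each and fatty acid oxidation in 15. Complex I passed in 13 and dynamics and mitophagy in 5. Each of these calls was lost when some single library was left out. Without vector 1 only protein import passed of the 6 (adjusted p = 0.0444), and without vector 2 or PTMA 2 only the tricarboxylic acid cycle (adjusted p = 0.0117 and 0.0443). Complex I turned to the lower direction without vector 2 (median -0.05, adjusted p = 0.983), and the median of the mitochondrial ribosome list was 0.04 without vector 1 (adjusted p = 0.0587), 0.01 without vector 2 (adjusted p = 0.223), 0.18 without vector 3 (adjusted p = 5.08e-12) and 0.04 without PTMA 2 (adjusted p = 0.0573). Dynamics and mitophagy also missed the threshold without PTMA 3 (adjusted p = 0.0525) and with libraries scaled to the same sum (adjusted p = 0.0568). The members with the smallest p-values had log2 fold changes of 0.22 (SE 0.08) for Mrps27, 0.17 (SE 0.06) for Idh3g, 0.23 (SE 0.08) for the protease Clpp, 0.24 (SE 0.09) for Cpt2, which imports fatty acids for oxidation, 0.19 (SE 0.07) for Ndufs7 and 0.16 (SE 0.06) for the cristae protein Immt.

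The lists of complexes II to IV (adjusted p = 0.0628), ATP synthase (adjusted p = 0.0966), mitochondrially encoded mRNAs (adjusted p = 0.191) and mitochondrial DNA maintenance (adjusted p = 0.606) did not pass camera. Without vector 3 the first 3 passed (adjusted p = 6.88e-06, 0.000113 and 0.000153), with medians of 0.146, 0.162 and 0.245 in place of 0.0239, 0.0456 and 0.0942. Complexes II to IV also passed without PTMA 1 or PTMA 3 (adjusted p = 0.0499 and 0.0368) and mitochondrially encoded mRNAs without PTMA 1 (adjusted p = 0.0135), while without vector 2 the medians of all 3 were below 0. Their members with the smallest p-values were Uqcrc1 (log2 fold change 0.18, SE 0.08), Atp5a1 (0.12, SE 0.06), mt-Co2 (0.12, SE 0.10) and Polg (-0.16, SE 0.12). No member of any mitochondrial list passed over all genes, and 0 passed adjusted over the list alone. Mitochondrially encoded mRNAs took 1.62%, 1.57% and 2.08% of the counts in vector 1 to 3 and 1.56%, 1.93% and 1.95% in PTMA 1 to 3. Vector 3 thus stood apart from its group, and PTMA 1 from its own, near vector 1 and vector 2. The mitochondrial ribosome list had 3213, 3140 and 3825 pooled CPM in the vector libraries and 3535, 3735 and 3449 in the PTMA libraries, with vector 3 above all 3 PTMA libraries.

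**Figure D2:**
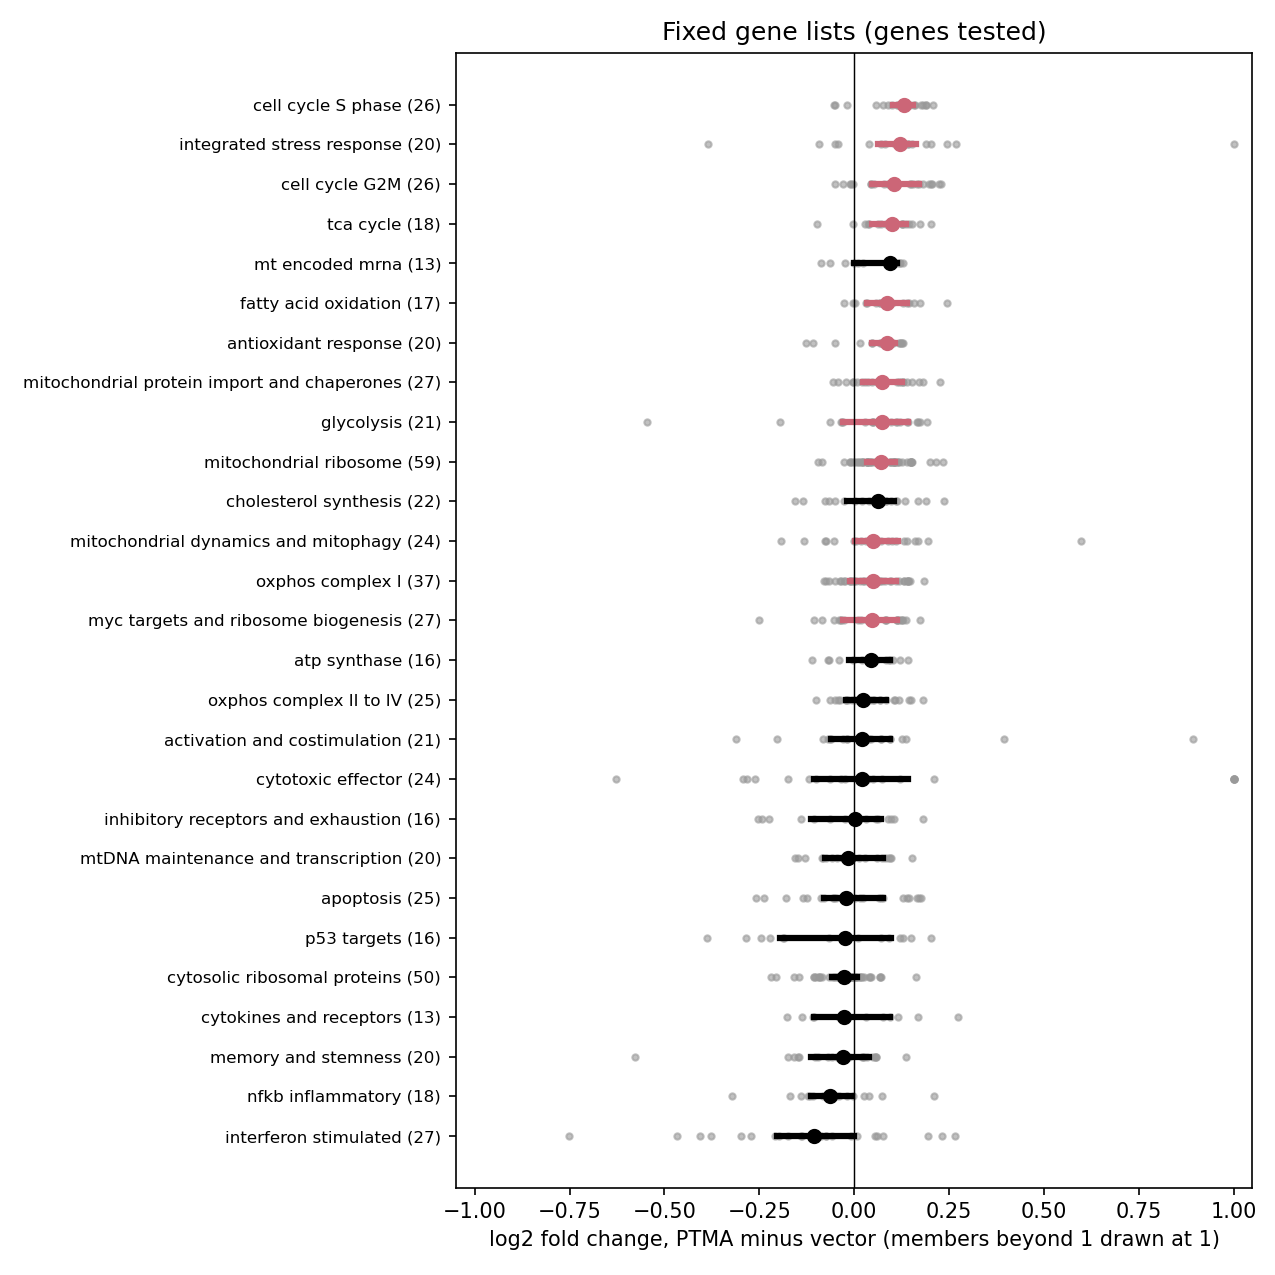
Log2 fold change, PTMA minus vector (horizontal axis), of the members of 27 gene lists fixed beforehand (vertical axis, with the number of genes tested). Grey points are genes, large points list medians and bars the quartiles; red marks the 12 lists that passed camera with a preset correlation, all with positive medians.

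Other metabolic and stress lists passed camera in the higher direction. They were the integrated stress response (16 of 20 members positive, adjusted p = 0.00312; adjusted p = 0.368 with an estimated correlation), glycolysis (15 of 21, adjusted p = 0.0237; adjusted p = 0.579 with an estimated correlation), Myc targets and ribosome biogenesis (19 of 27, adjusted p = 0.0276; adjusted p = 0.411 with an estimated correlation) and the antioxidant response (17 of 20, adjusted p = 0.0276; adjusted p = 0.651 with an estimated correlation). Within glycolysis, the hexokinase gene Hk2 lay in the other direction, at 9.33 ± 0.59 and 6.39 ± 1.21 CPM (SD, n = 3 per group) in vector and PTMA. Psat1 of serine synthesis had a log2 fold change of 0.20 (SE 0.07), Polr1a of -0.25 (SE 0.12) and Prdx2 of 0.13 (SE 0.06). Cholesterol synthesis (adjusted p = 0.0957, Fdft1 at 0.19, SE 0.07) and cytosolic ribosomal proteins (adjusted p = 0.925, Rpl38 at -0.22, SE 0.14) did not pass. The cytosolic ribosomal list passed in opposite directions when a library was left out, higher without vector 3 (adjusted p = 3.1e-07) and lower without vector 2 (adjusted p = 0.00128), and it was lower with quantile normalization (adjusted p = 0.00141). In all, 12 of 27 lists passed camera, 0 with an estimated correlation and 2 by fry, and no member passed over all genes or adjusted over the list alone. The number of lists was 5 without vector 1, 6 without vector 2 and 4 without PTMA 2. Of the 4 metabolic and stress lists, glycolysis lost its call without vector 3, PTMA 1 or PTMA 3 (adjusted p = 0.254, 0.145 and 0.0511), and the integrated stress response without PTMA 2 (adjusted p = 0.0573). Myc targets lost theirs without vector 1, vector 2, PTMA 2 or PTMA 3 (adjusted p = 0.0989, 0.118, 0.115 and 0.102), and the antioxidant response without vector 1, vector 2 or PTMA 2 (adjusted p = 0.192, 0.267 and 0.271). Glycolysis, Myc targets and the antioxidant response also missed the threshold with libraries scaled to the same sum (adjusted p = 0.059, 0.059 and 0.0568).

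Lists of T cell function did not pass camera on the counts. With limma on log2(FPKM + 1) and a mean FPKM of at least 5, those of interferon-stimulated genes (adjusted p = 0.0279), NF-κB and inflammation (adjusted p = 0.0442) and cytokines and receptors (adjusted p = 0.04) passed in the lower direction. Interferon-stimulated genes had 20 of 27 members negative and a median log2 fold change of -0.10 (camera adjusted p = 0.0966; fry adjusted p = 0.0235); the antiviral gene Ifit1 was at 2.49 ± 0.43 and 1.48 ± 0.41 CPM (SD, n = 3 per group). Cytotoxic effectors (adjusted p = 0.17) had 14 of 24 members positive, and the granzyme gene Gzmf stood near the floor, at 0.06 ± 0.05 and 0.50 ± 0.25 CPM (SD, n = 3 per group). Activation and costimulation (adjusted p = 0.426, Nr4a3 at -0.31, SE 0.12), NF-κB and inflammation (adjusted p = 0.537, Tnfaip3 at -0.14, SE 0.07) and inhibitory receptors (adjusted p = 0.925, Eomes at -0.22, SE 0.09) did not pass. Nor did memory and stemness (adjusted p = 0.606), where Klf3 stood at 8.62 ± 1.43 and 5.77 ± 0.57 CPM (SD, n = 3 per group), or cytokines and receptors (adjusted p = 0.925, Il12rb1 at 0.27, SE 0.14). Apoptosis (adjusted p = 0.841, Apaf1 at -0.24, SE 0.10) and p53 targets (adjusted p = 0.738, Btg2 at -0.24, SE 0.09) did not pass either.

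Of 2215 GO and KEGG terms, 54 passed camera, 53 higher and 1 lower. The smallest p-values were those of DNA replication (KEGG, 35 genes, median log2 fold change 0.14, adjusted p = 1.09e-05; adjusted p = 0.993 with an estimated correlation) and the proteasome (KEGG, 45 genes, median 0.09, adjusted p = 0.000553; adjusted p = 0.993 with an estimated correlation). Ubiquinone biosynthesis (15 genes, median 0.12, adjusted p = 0.00517; adjusted p = 0.993 with an estimated correlation) and arginine and proline metabolism (35 genes, median 0.11, adjusted p = 0.00517; adjusted p = 0.993 with an estimated correlation) followed. The term lower in the PTMA libraries was keratinization (31 genes, median -1.55, adjusted p = 0.0232; adjusted p = 0.993 with an estimated correlation). No term passed with an estimated correlation or by fry. The number of terms was 5 without vector 1, 6 without vector 2, 174 without vector 3, 1 without PTMA 2 and 35 without PTMA 3.

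Of 7 lists of cell type markers 6 could be tested and none passed camera. They were T cell receptor and CD8 (adjusted p = 0.353), CD4 and regulatory T cells (adjusted p = 0.975), B cells (adjusted p = 0.299), myeloid and dendritic cells (adjusted p = 0.299), NK cells (adjusted p = 0.975) and stroma (adjusted p = 0.885); the erythroid list had under 5 tested genes. Median, mean and camera direction differed in sign for the B cell, NK cell and CD4 lists, and likewise for the lists of cytosolic ribosomal proteins, mitochondrial DNA maintenance, apoptosis, cytokines and inhibitory receptors. Genes of other cell types, chosen after their values were seen, did differ between libraries. A set of 14 oocyte genes, Gdf9 among them, had a pooled level of 114 ± 12.3 CPM in the vector and 19.7 ± 2.51 CPM in the PTMA libraries (SD, n = 3 per group). A set of 5 genes of mature dendritic cells had 1.91 ± 0.77 and 11.3 ± 1.37 CPM (SD, n = 3 per group). The keratinization term followed libraries and not groups: keratin Krt14 was at 15.2 CPM in vector 2, 18.4 CPM in vector 3 and 5.99 CPM in PTMA 1, and had a count of 0 in the other libraries, which allows up to 0.0546 CPM.

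**Figure D3:**
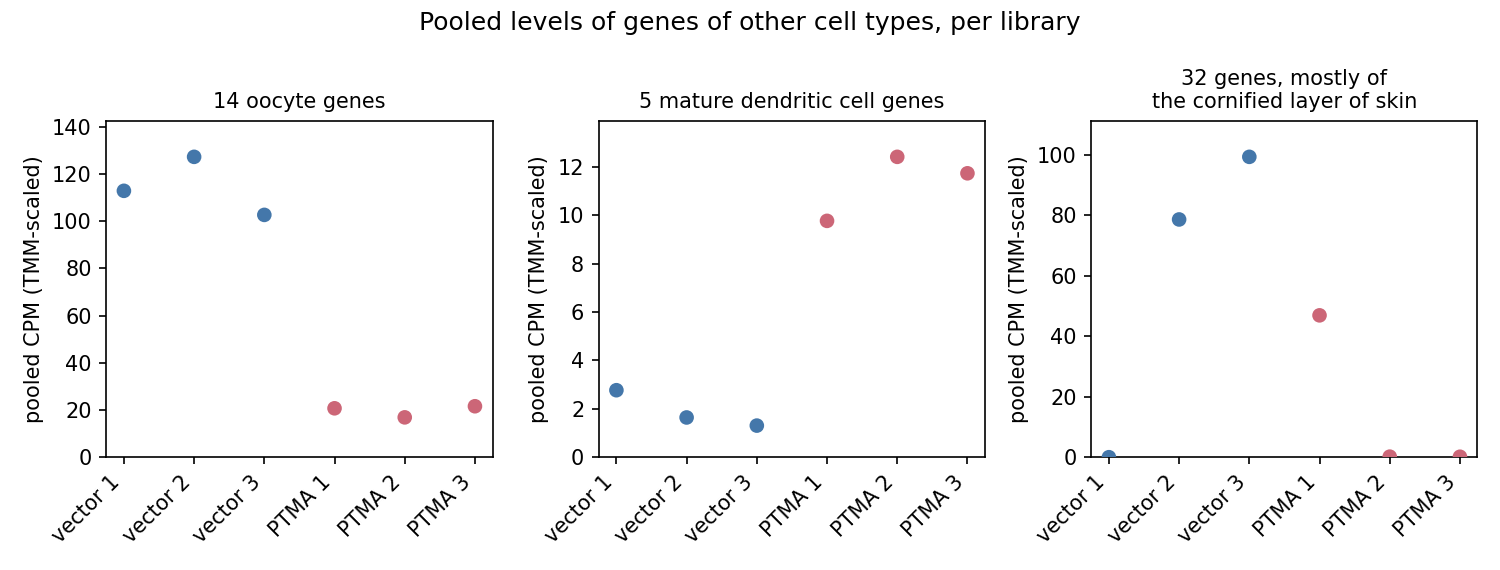
Pooled level in TMM-scaled CPM (vertical axes, from 0) of 3 sets of genes chosen after their values were seen, in each of the 6 libraries (horizontal axes, vector in blue and PTMA in red). The oocyte genes lie higher in the vector libraries, the dendritic cell genes in the PTMA libraries, and 32 genes, mostly of the cornified layer of skin, in vector 2, vector 3 and PTMA 1.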

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

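Most calls depended on the processing; the cause was not tested unless stated. The number of changed genes was 2, and all of them at least 2-fold, under median-of-ratios size factors, under libraries scaled to the same sum (also without Ptma and mitochondrially encoded genes) and with robust edgeR. With no filter on low counts it was 0 in edgeR and 0 in limma on log2(FPKM + 1), where more genes were tested. Limma on log2(FPKM + 1) called 1 gene, at least 2-fold, also with a pseudocount of 0.1 or 0.5, with a mean FPKM of at least 0.1 and with no trend. It called 0 with a mean FPKM of at least 5 and 0 with quantile normalization. Array weights gave 29 genes, 15 at least 2-fold, and DESeq2 gave 42, 35 at least 2-fold (7 higher, 35 lower). Leaving out each library in turn gave 0 to 3 genes, 0 to 3 at least 2-fold, 4 to 15 lists, 1 to 174 terms and a Ptma log2 fold change of 0.34 to 0.62. The Ptma log2 fold change lay between 0.34 and 0.62 in all 22 alternatives and passed the threshold only with array weights (0.57, adjusted p = 0.0227; other alternatives 0.0724 to 1). Gdf9 was tested in 21 alternatives, was negative in all of them and passed in 14. Pkd2l2 was tested in 15, was negative in all of them and passed in 5. Lists past the threshold numbered 4 with quantile normalization, 0 with an estimated correlation and 2 with fry. Terms numbered 101 with a mean FPKM of at least 0.1, 147 with no filter on FPKM, 30 with a mean FPKM of at least 5, 10 with quantile normalization, 110 with array weights, and 0 with an estimated correlation and 0 with fry. Same-numbered libraries did not deviate together (correlations of -0.12, -0.16 and -0.12). This gives no sign that the numbers pair the samples, but it cannot exclude a shared animal or culture. A replicate block gave 0 genes, 0 at least 2-fold, 7 lists, 4 terms and 0.46 for Ptma. Robust edgeR and no trend do not alter the values camera uses, and DESeq2 gives none for it, so these were not run for lists or terms. The scaling, robust, block and leave-one-out fits were made on counts, the pseudocount, FPKM filter, quantile, trend and weight fits on FPKM. At this depth, genes below 0.0546 CPM in a library cannot be told from 0.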

Other observations

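The sequencing depth test, the granulosa test, the counts over splits and the comparison of the MHC class II genes with the gain of the dendritic genes, with its margin of 2 SE, were chosen only after the results were seen, and the oocyte and dendritic gene lists were written after the genes with the smallest p-values had been seen. Of 33 genes with an unadjusted p under 0.001, where chance gives 16.6, 27 were lower and 6 higher in the PTMA libraries. Among the 27 were 12 genes of the oocyte lists. Bmp15, an oocyte growth factor related to Gdf9, stood at 2.06 ± 1.02 and 0.08 ± 0.04 CPM (SD, n = 3 per group) in vector and PTMA, the linker histone gene H1f8 at 22.2 ± 3.09 and 2.47 ± 1.88 CPM, and Obox1 at 11.6 ± 3.55 and 1.80 ± 0.86 CPM. Ooep had a count of 0 in the PTMA libraries and was at least 52.0-fold lower there, against a floor of 3 counts over the group. None of these 4 genes passed the test (edgeR, adjusted p = 0.116 for Bmp15, 0.17 for H1f8, 0.116 for Obox1 and 0.116 for Ooep).

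Among the 6 higher genes 4 belonged to the dendritic lists. Ccl22, a chemokine of mature dendritic cells, stood at 1.22 ± 0.76 and 6.76 ± 1.44 CPM (SD, n = 3 per group) in vector and PTMA, and the actin-bundling gene Fscn1 at 0.25 ± 0.15 and 1.71 ± 0.18 CPM. The costimulatory receptor gene Cd40 had a count of 0 in the vector libraries and was at least 20.2-fold higher in the PTMA libraries, against a floor of 3 counts over the group. None passed the test (edgeR, adjusted p = 0.199 for Ccl22, 0.318 for Fscn1 and 0.318 for Cd40).

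Oocyte genes were lower in the PTMA libraries. The PTMA libraries were deeper, with 1.09 times the counts of the vector libraries, which argues against depth. Testis genes had 0.013 of the oocyte genes' pooled level, and the excess of 7 granulosa and stroma genes under 5 CPM in the PTMA libraries was 0.0028 of that of the oocyte genes, which argue against testis and against granulosa or stroma. Of 14 embryonic genes listed, 3 were among the deposited genes and 1 was tested, Eif1a (log2 fold change 0.00). Tcstv1 (0.12 CPM in vector and 0.12 CPM in PTMA) and Tcstv3 (0.08 and 0.02 CPM) were too low to be tested. At 100.2 CPM in vector and 100.5 CPM in PTMA, Eif1a would hide a small share of embryonic RNA, so such RNA was not tested. RNA of oocytes in the vector libraries is a candidate explanation: 41 tested oocyte genes not seen beforehand had a median log2 fold change of -1.38, 35 of them negative, although 3 are at 5 CPM or more in the PTMA libraries and Zp3 was at only 1.10 ± 0.84 CPM (SD, n = 3) in the vector libraries. Whether a single source supplied them stays open (the labels name no sort or gate). The log2 ratios of a vector library to the vector mean differed between genes by an SD of up to 0.578, under the bound of 1 that would exclude a single source. The median correlation of a gene with the pooled level of the others over the 3 vector libraries was 0.456, short of the 0.8 that a single source predicts. That correlation cannot decide, since a large part of the pooled level was Rnf114, at 229.5 CPM in vector and 240.9 CPM in PTMA. An effect of PTMA on these genes, as the groups would give, was not tested. Nor was carry-over of reads from other samples, for which raw reads are needed.

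The 5 mature dendritic cell genes chosen after their values were seen were higher in the PTMA libraries. More RNA of antigen-presenting cells is a candidate explanation that the tables do not decide: Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had a median log2 fold change of 0.234, under the bound of 0.5 that was to count against it, but that bound was wrong for Cd74 and H2-Ab1, whose vector levels of 18.5 and 28.3 CPM exceed the 9.4 CPM that the 5 dendritic genes gained, and only 1 of the 4 lay under it by more than 2 SE. Cd74 gained 3.7 CPM (SE 2.1) and H2-Ab1 4.3 (SE 1.8), while H2-Eb1 gained 0.59 (SE 0.59) from 1.91 and H2-Aa 0.042 (SE 0.25) from 0.33, which speaks against such RNA unless its MHC class II mRNA was low. The 35 dendritic genes tested besides those 5 had a median log2 fold change of 0.04 (22 positive, 13 negative). This fell short of the median above 0.5 that was predicted if such RNA were the cause. However, 16 of the 35 were at 5 CPM or more in the PTMA libraries, which would hide a small share, so this median cannot decide. Among the rarer ones Flt3 was 6.28-fold (log2 fold change 2.62, SE 1.23) and Anxa3 2.56-fold (1.35, SE 0.42) as high, but the groups overlapped for Flt3. Zbtb46 and Ciita were lower (log2 fold changes of -0.53, SE 0.35, and -0.99, SE 1.03). Il12b and Ccl17, too low to be tested, had 0 counts in vector against 33 and 12 in PTMA. None of the 5 genes chosen after their values were seen passed the test (edgeR, adjusted p = 0.199 to 0.807). Such RNA, an effect of PTMA on these genes and a rise by chance cannot be told apart. Carry-over of reads from other samples was not tested here either.

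The S phase and G2M lists and 6 mitochondrial lists passed camera in the higher direction with the preset correlation, and none passed with an estimated one. For the 6 mitochondrial lists past the threshold, the largest mean log2 difference among the other 9 splits of the libraries, 3 against 3, was 2.22 times the real one (0.153 against 0.069), which is consistent with variation between libraries that does not follow the groups. For G2M that ratio was 0.937 (0.0993 against 0.106) and for S phase 0.538 (0.063 against 0.117), neither of which decides. Each other split exchanges a single library per group and so keeps part of any real difference. The ratio could therefore hardly fall under the bound that was to count against such variation, however large the difference. Such variation and an effect of PTMA thus cannot be told apart for these lists.

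The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For changed genes 2 of the 10 splits gave as many, with 2 in the real split and at most 33 in another, and for those at least 2-fold 2 of the 10, with 2 and at most 32. For lists 3 of the 10 gave as many, with 12 and at most 14, and for terms 3 of the 10, with 54 and at most 140. The 33 genes were called with vector 1, PTMA 2 and PTMA 3 on one side, which points to a structure of the samples other than the groups. Of them 32 were higher in vector 2, vector 3 and PTMA 1, mostly genes of cornified skin such as Sprr1a, and also the keratin genes Krt14 and Krt16. The pooled levels of the 32 genes were 78.6, 99.3 and 46.9 CPM against at most 0.184 CPM in the other libraries.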
